A study of Mus musculus with 8 samples.

How the data were processed

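Liver RNA of 4 WT and 4 TrxR1/Gsr-null female mice, 4 weeks old, was measured on 1 Affymetrix 3′ array each. Per the labels' protocols, total RNA was extracted with a RiboPure kit and amplified and biotin-labelled with a MessageAmp kit. The deposited table holds 1 log2 expression value per probe set and array. Per the submitters' processing notes the authors used GCRMA, a method that usually corrects background by probe sequence, quantile-normalizes arrays and summarizes probe sets; its version and settings are not given in the sources used here. The log2 scale was read from the deposited values, which ran from 0.53 to 14.6, since no label states it. GCRMA pulls values near background together, so folds of genes that are near background in one group depend on that correction. The median log2 value of an array was between 3.56 and 3.78. An array gives no sampling depth, and the number of arrays limits the precision.

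Of 22690 probe sets, 64 are control probe sets, 20380 are paired with 1 gene symbol in the platform annotation, 691 with several and 1555 with none. Symbols were updated through gene identifiers in a RefSeq table of the assembly GRCm38.p6 (20364 identifiers matched), which was used only for names and for the order of genes, and no coordinates are given because no build is named for the array. Probe sets with several genes or none were left out of the gene tests. Where a gene had several probe sets, those ending in _x_at were set aside if another kind existed, and the one with the highest mean over all 8 arrays was kept, giving 12393 genes. Genes among the lowest 40% by mean over all arrays (log2 value up to 3.38, called the low-value limit) were left out unless at least 4 arrays exceeded that limit, which kept 98 more genes and left 7534.

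Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 2 groups, no covariates, two-sided, Benjamini-Hochberg adjustment), and a gene was called at an adjusted p below 0.05. The targeted genes and the H2 genes were also tested over all 22690 probe sets less the 64 controls, without the filter on low values. Counts of called probe sets used the 13776 that passed that filter. The 39 gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Camera asks whether a list moved relative to all other genes, fry whether its genes moved one way on balance. At an adjusted p below 0.05, camera called 18 lists, fry 19 and camera with an estimated correlation 1. The p-values given as adjusted over the list alone used only a list's measured members.

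Tests, lists, the choice of probe set, the filter and the rule for named genes were set before the data were examined. The rule took Txnrd1 and Gsr, the 12 called genes with the largest rise and the 12 with the steepest fall whose groups did not overlap (genes known only by a clone or predicted name passed over), up to 4 called members of each list per direction with the smallest adjusted p, and, to describe a list, its first 3 members as written where uncalled. It gave 180 genes. Those in the text were chosen from them, mostly among those called with each array left out in turn, after their values were seen, as were all genes named outside the rule.

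Where a list had no call, counts at an unadjusted limma p are given. The fitting and list tests were checked on simulated data with the arrays' own means and spreads, 4 against 4, over 7534 genes with 200 changed. The simulated genes were drawn independently of each other, so the check shows nothing about list tests on genes that vary together. Of genes changed by 0.5, 1 and 2 log2 units, 3.25%, 37.6% and 86.7% were called, with 5.19% false calls. So most changes of up to 2-fold go uncalled in this design, as do some changes of 2 log2 units, and a gene that was not called may still differ.

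Each array was compared with the others before averaging. No 2 arrays held identical values, and the highest correlation between 2 arrays was 0.994. The replicate numbers come from the sample titles and are shared by the groups. Deviations from the group means of all 4 same-numbered pairs correlated at 0.21 to 0.37, so the numbers were taken to pair the samples and a fit with the replicate number as a block (replicate block) is given where it changes a call. The 4 pairs of other number within replicates 1 and 2 or within replicates 3 and 4 correlated as much (mean 0.28 against 0.28), and 5 of 8 arrays correlated best with their own number, so the shared structure separates replicates 1 and 2 from replicates 3 and 4. Of 18 labelled spike-in control probe sets above the low-value limit, 3 separated these sets of 4 arrays without overlap, none separated the genotypes, and 3 of the 35 splits into 4 and 4 had as many. The labels name separate animals for the 2 genotypes and give no batch.

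Alternatives were the filter, the probe sets per gene, the scaling between arrays, a floor on low values, the variance model, array weights, the replicate block, leaving out each array in turn, the thresholds, the list test and the window of neighbouring genes. Fits with replicates 1 and 2 against 3 and 4 as a block or taken separately, and without WT replicates 3 and 4, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.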

Results

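Livers of 4-week-old female mice on a C57BL/6J background were profiled on Affymetrix 3′ expression arrays, 1 array per animal, in 4 wild-type (WT) animals and 4 TrxR1/Gsr-null animals. The labels name each array as a biological replicate and give 1 factor, the genotype. TrxR1, encoded by Txnrd1, is the cytosolic thioredoxin reductase and Gsr is glutathione reductase, the NADPH-dependent enzymes that reduce the thioredoxin and glutathione pools of the cytosol, and the label names the livers as null for both. The submitters' title names the Nrf2 response, the induction by the transcription factor Nrf2 of genes that act against oxidants and electrophiles. All livers were taken in the late morning. Values are log2 expression after GCRMA, and folds are powers of 2 of the log2 difference between group means. An array gives no count of molecules, and the number of arrays, 4 per group, limits the precision that can be stated. A difference was called when its adjusted p was below 0.05.

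The question of the first comparison was whether the targeted genes differ between the groups as labelled. Gsr was lower in TrxR1/Gsr-null liver in both of its probe sets, and Txnrd1 was higher in the single probe set that stood above background. The brighter Gsr probe set fell from 7.16 ± 0.09 (SD, n = 4) in WT to 6.01 ± 0.22 (SD, n = 4) in the null livers, 2.23-fold lower, with adjusted p = 0.00397. The other Gsr probe set averaged 5.81 ± 0.42 in WT and 4.64 ± 0.21 in the null livers, 2.24-fold lower, with adjusted p = 0.0225 over all probe sets. The Txnrd1 probe set rose from 9.82 ± 0.17 to 11.92 ± 0.19 (SD, n = 4 each), 4.31-fold, with adjusted p = 0.000115. The 4 WT values of this probe set lay between 9.56 and 9.93 and the 4 null values between 11.65 and 12.07. The other 2 Txnrd1 probe sets had group means from 1.76 to 2.12, all below the low-value limit of 3.38, and with the mean of all 3 probe sets the Txnrd1 difference was 0.78 on the log2 scale in place of 2.11. The labels do not say which part of either gene was deleted, and a probe set outside the deleted part checks no label.

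**Figure D1:**
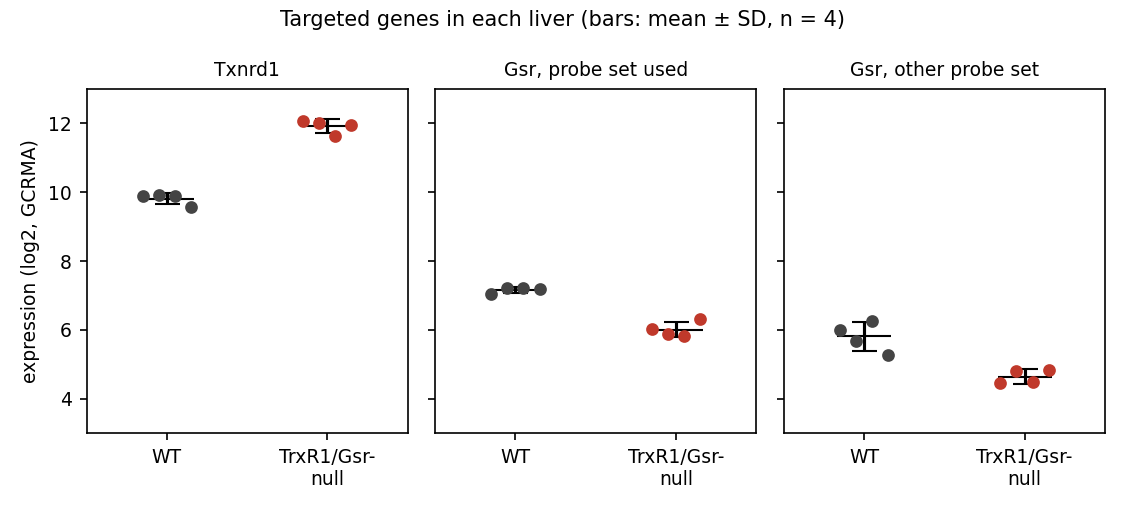
Expression (log2, GCRMA) of the brightest Txnrd1 probe set and of both Gsr probe sets in each of the 4 WT and 4 TrxR1/Gsr-null livers. Points are animals and bars are mean ± SD; the 4 null values of Txnrd1 lie above and the 4 null values of each Gsr probe set lie below all WT values.

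Xist, the transcript of the inactive X chromosome, had a log2 value of at least 11.1 at its brightest probe set in all 8 livers, and the 6 probe sets of Y-linked genes reached at most 3.69. The labels name all animals as female.

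Across the liver transcriptome, 337 genes were called higher and 162 lower in TrxR1/Gsr-null liver among 7534 tested. Cbr3, a carbonyl reductase, rose 270-fold (log2 difference 8.08 ± 0.40 SE), with 2 of its 4 WT values below the low-value limit. Nqo1, a quinone reductase, rose 24.0-fold, Srxn1, which repairs overoxidized peroxiredoxins, 22.7-fold, Aox1, an aldehyde oxidase, 16.4-fold, and Slc48a1, a heme transporter, 13.8-fold. Among the steepest falls were those of Cyp4a14, a fatty acid hydroxylase (19.9-fold lower, log2 difference -4.32 ± 0.72 SE, and 10.6-fold without TrxR1/Gsr-null replicate 2), H2-K1, a class I histocompatibility gene (12.2-fold at its brightest probe set, and 2.41- to 8.56-fold at its other 3), Erdr1 (11.9-fold), Rgs16, a regulator of G protein signalling (10.2-fold), and Defb1, a beta-defensin (9.42-fold).

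Among called genes whose groups did not overlap, clone names passed over, the 12 with the largest rise also held Ly6d, a cell surface protein (86.8-fold), the glutathione peroxidase Gpx2 (52.1-fold), Bex1 (26.9-fold), the microsomal glutathione transferase Mgst2 (21.6-fold), Snhg11, a noncoding RNA (21.0-fold), Gipc2 (15.5-fold) and the fetal serum protein Afp (14.8-fold, and 23.4-fold without TrxR1/Gsr-null replicate 3). WT means of Ly6d, Gpx2, Bex1, Mgst2 and Snhg11 lay below the low-value limit of 3.38, as did 2 WT values each of Cbr3 (2.97 and 2.92) and Afp and 1 of Gipc2, so these folds depend on how the background was estimated. The 12 with the steepest fall also held Apon, an apolipoprotein (8.11-fold lower), Trim34a (7.06-fold), Igfbp2, an insulin-like growth factor binding protein (6.66-fold), the drug-inducible cytochrome Cyp2b10 (6.02-fold), the organic anion transporter Slco1a4 (5.99-fold), the phosphatidate phosphatase Lpin1 (5.87-fold) and the clock repressor Bhlhe40 (5.83-fold). The calls of H2-K1 (adjusted p = 0.0378) and Trim34a (adjusted p = 0.0431) were lost when any one of the 4 WT arrays or TrxR1/Gsr-null replicate 1 or 3 was left out (adjusted p up to 0.0986 and 0.114), and with no filter on low values (adjusted p = 0.0638 and 0.0701). The fold of H2-K1 was 7.34 without TrxR1/Gsr-null replicate 1 and 21.0 without replicate 4 of that group, and that of Trim34a was 4.42 without replicate 1. Trim34a was not called with array weights (adjusted p = 0.0665) or the mean of its probe sets (adjusted p = 0.0652) either. The other 22 of these 24 genes were called with each array left out in turn.

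Of the calls, 255 higher and 101 lower genes differed at least 2-fold, and 336 of the higher and 158 of the lower genes had no overlap between the 4 values of one group and those of the other. Over all tested genes 16.6% showed no overlap, against 2.86% by chance if the 8 arrays were exchangeable, a value that leaves out the shared structure of the replicate numbers. Higher genes made up 67.5% of the calls, but 53.6% after a further quantile normalization (313 higher, 271 lower) and 49.7% with each array centred on its median (285 higher, 289 lower), which moved the median difference of all genes by -0.11 and -0.17 on the log2 scale, from 0.096 to -0.01 and -0.07. The direction of a small difference depends on the scaling, and calls were not made relative to that median in any of them. Left-out arrays moved a count by over 1.5 times in 5 cases, with 277 higher and 101 lower without WT replicate 2, 217 and 89 without WT replicate 3, 211 and 75 without TrxR1/Gsr-null replicate 1, 196 and 81 without replicate 2 and 210 and 111 without replicate 4 of that group.

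**Figure D2:**
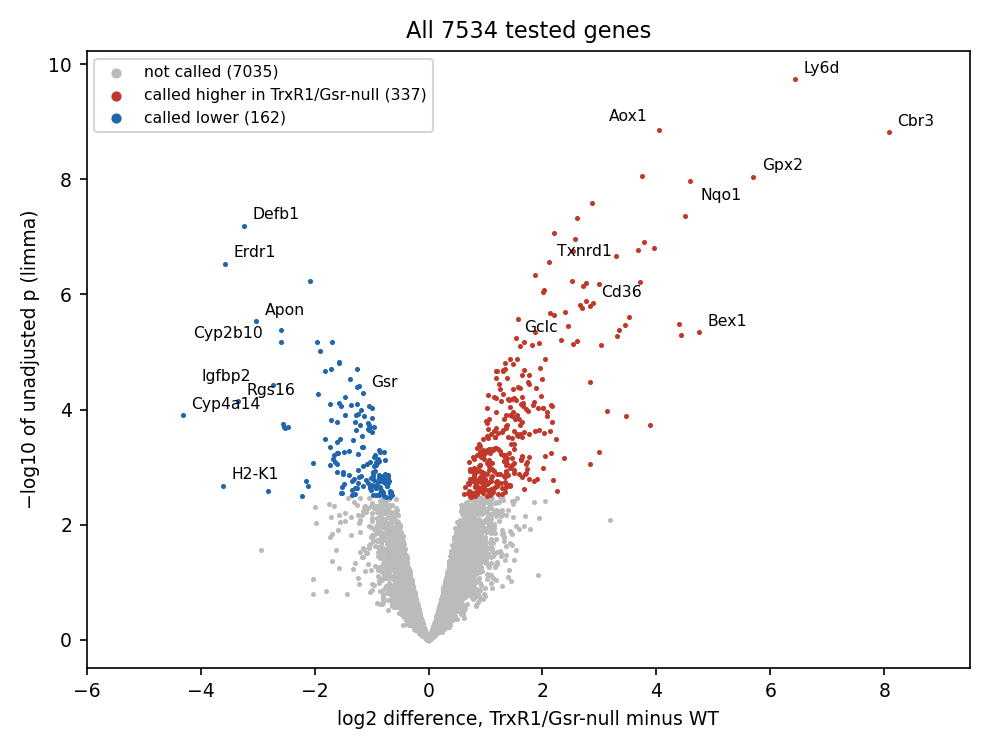
Log2 difference between TrxR1/Gsr-null and WT liver (horizontal) against −log10 of the unadjusted limma p (vertical) for each of the 7534 tested genes. Red points are the 337 genes called higher and blue points the 162 called lower; the rises extend to a log2 difference of 8.08 (Cbr3) and the falls to -4.32 (Cyp4a14).

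The arrays themselves were not alike. WT replicates 3 and 4 had narrower distributions than the rest, with interquartile ranges of 3.96 and 3.74 log2 units against 4.30 to 4.43 on the other 6 arrays, and the mean of the controls that should be absent was 2.23 and 2.42 there against 1.70 to 1.86 elsewhere. The Actb probe sets at the 3′ and 5′ ends, a sign of RNA quality, differed by 1.498 and 1.57 log2 units on these arrays and by 1.76 on TrxR1/Gsr-null replicate 3, against 1.01 to 1.17 on the other 5. The same difference for Gapdh was -0.32 and -0.23 on WT replicates 3 and 4 and -0.35 on TrxR1/Gsr-null replicate 3. It was -0.70 to -0.26 on the other 5, so Gapdh did not separate these 3 arrays from the rest. Without both WT arrays 187 genes were called higher and 138 lower, and 36 of 180 named genes lost their call and 2 gained one. Of the genes in the text, Afp, Angptl4, Bhlhe40, Dbp, H2-K1, Hspb1, Lpin1, Pck1, Srebf1, Tef, Trim34a, Txnip and Usp18 were then not called (adjusted p from 0.0535 to 0.177), and Pecam1 was (adjusted p = 0.0378). A loss of calls was not particular to these 2 arrays. Leaving out other pairs of a group gave from 86 higher and 21 lower (TrxR1/Gsr-null replicates 1 and 4) to 1001 and 243 (WT replicates 1 and 2). Replicates 1 and 2 also differed from replicates 3 and 4 across both genotypes, with 799 genes called between them given the genotype, and the labels name no batch. With that split as a block, chosen after seeing the data, 647 genes were called higher and 334 lower, and the genotypes compared within replicates 1 and 2 gave 266 and 236 and within replicates 3 and 4 gave 162 and 30.

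Genes known as targets of Nrf2 rose as a group (camera adjusted p = 1.5e-25). Of 33 measured members of the list, 24 were called higher and none lower, and 31 of the 33 differences were positive, with a median log2 difference of 1.96. Besides Cbr3, Gpx2, Nqo1, Srxn1 and Aox1, the members included Gsta2, a glutathione transferase (9.75-fold), Cbr1, a carbonyl reductase (6.57-fold), Ugdh, which makes UDP-glucuronate (6.11-fold), and Blvrb, a biliverdin reductase (5.94-fold). Adjusted over the list alone, 28 members were higher and 2 lower. The list remained called with an estimated correlation (adjusted p = 0.025), the only one of the 39 lists to do so, and by fry (adjusted p = 9.4e-06). Within replicates 1 and 2 alone, 24 members were called higher and 1 lower, and within replicates 3 and 4 alone 20 were called higher and 0 lower.

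**Figure D3:**
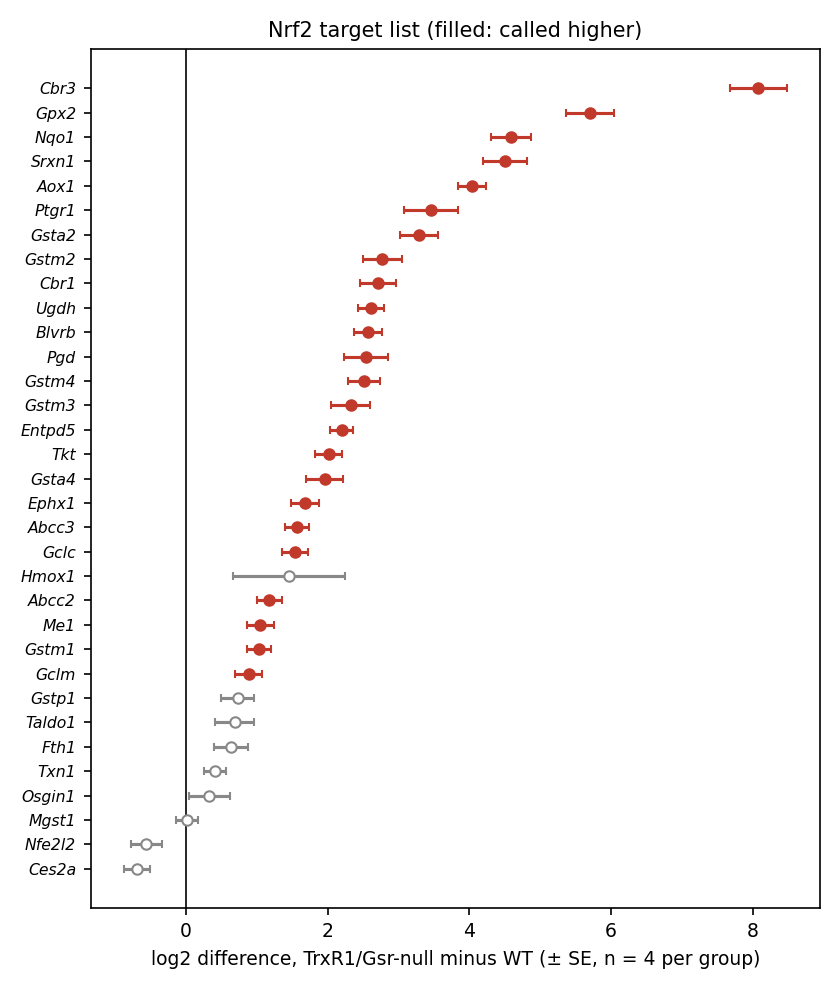
Log2 difference between TrxR1/Gsr-null and WT liver (horizontal, ± SE, n = 4 per group) for each of the 33 measured members of the Nrf2 target list (vertical). Filled points are the 24 members called higher, and open points the 9 not called, of which 2 lie below 0.

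Genes that use and make glutathione were called higher more often than lower. Among glutathione transferases 8 of 20 were called higher and none lower, with a camera adjusted p of 0.000148, and 0.267 with an estimated correlation. They included Mgst3 (6.45-fold) and Gstm4 (5.71-fold). Adjusted over the list alone, 10 were higher and 2 lower. In glutathione synthesis and turnover 4 of 12 were called higher and none lower (4 and 1 with the replicate block; 2 higher without WT replicate 2 or TrxR1/Gsr-null replicate 1 or 4). This list had a camera adjusted p of 0.0139, and 0.238 with an estimated correlation. Gclc, the catalytic subunit of the rate-limiting ligase, rose 2.90-fold and Gss, the glutathione synthetase, 2.84-fold. Adjusted over the list alone, 4 were higher and 1 lower. Without their members that are also on the Nrf2 list, neither the transferases (adjusted p = 0.589) nor glutathione synthesis (adjusted p = 0.173) were called.

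Some genes of NADPH supply were called higher and none lower. Of 14 genes of the pentose phosphate pathway and NADPH supply 4 were called higher, Pgd (5.83-fold), Tkt (4.04-fold), Nnt (2.26-fold) and the malic enzyme Me1 (2.07-fold), with the same counts when adjusted over the list alone. Nnt carries a deletion in C57BL/6J mice, and whether its rise is a difference of strain was not tested. The camera adjusted p was 0.0404, and 0.218 with an estimated correlation. The call was lost with the replicate block (adjusted p = 0.0587), without TrxR1/Gsr-null replicate 3, WT replicate 1 or WT replicate 2 (adjusted p up to 0.0924), without Nrf2 list members (adjusted p = 0.906) and without probe sets that can match several transcripts (adjusted p = 0.0958). In the thioredoxin, peroxiredoxin and glutaredoxin family 3 of 21 were called higher and 1 lower (4 and 2 adjusted over the list alone, 2 to 3 and 0 to 1 with 1 array left out; camera adjusted p = 0.496, fry adjusted p = 0.0451). Txnip, a thioredoxin-binding protein, was the member called lower, 1.89-fold (adjusted p = 0.0369), and the call was lost without any one of WT replicates 2, 3 and 4 and TrxR1/Gsr-null replicates 1, 2 and 3 (adjusted p up to 0.105). Thioredoxin itself, Txn1, averaged 11.97 in WT and 12.38 in the null livers and was not called (adjusted p = 0.146), though it was with array weights (adjusted p = 0.0305) and with a trended, robust prior (adjusted p = 0.0319). For hydrogen peroxide and superoxide removal 3 of 15 were called higher and 1 lower, with the same counts when adjusted over the list alone and 2 to 3 and 0 to 1 with 1 array left out (camera adjusted p = 0.692, fry adjusted p = 0.0104). Gpx4, which reduces lipid peroxides, rose 2.14-fold. In the methionine cycle, transsulfuration and cysteine catabolism 3 of 20 were called lower and none higher (4 lower adjusted over the list alone; 0 to 2 lower with 1 array left out), with a camera adjusted p of 0.0148, and 0.218 with an estimated correlation. Cbs, which takes homocysteine into cysteine synthesis, fell 1.89-fold (adjusted p = 0.0217), a call lost without WT replicate 2, TrxR1/Gsr-null replicate 2 or replicate 4 of that group (adjusted p up to 0.0661). That list's camera call was lost in 3 separate settings: without WT replicates 3 and 4 (adjusted p = 0.0678), after quantile normalization (adjusted p = 0.066), and without probe sets that can match several transcripts (adjusted p = 0.115). Cbs is also among the called neighbours of the H2 genes described below, and whether its fall is a difference of strain was not tested.

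In drug metabolism, conjugation enzymes were called higher more often than lower. Of 16 conjugation enzymes other than glutathione transferases 5 were called higher and 1 lower, with the same counts when adjusted over the list alone and 2 and 1 without TrxR1/Gsr-null replicate 4. The camera adjusted p was 0.0391, and 0.334 with an estimated correlation. The call was lost with the replicate block (adjusted p = 0.056), and without TrxR1/Gsr-null replicate 3, WT replicate 1 or WT replicate 2 (adjusted p up to 0.124), without Nrf2 list members (adjusted p = 0.181) and with the lowest 60% of genes left out (adjusted p = 0.051). Tpmt, a thiopurine methyltransferase, rose 3.14-fold, a call lost without probe sets that can match several transcripts (adjusted p = 0.0854). Of 17 transporters 4 were called higher and 2 lower (5 and 5 adjusted over the list alone, 4 and 4 with the replicate block, 4 to 5 and 1 to 3 with 1 array left out; camera adjusted p = 0.972, fry adjusted p = 0.0176). The efflux pumps Abcc5, at 13.5-fold from a WT mean below the low-value limit, and Abcg2, at 3.63-fold, were higher, opposite to the uptake carrier Slco1a4. Of 25 aldehyde and ketone reductases and dehydrogenases 4 were called higher and 2 lower (7 and 2 adjusted over the list alone, 4 and 1 with the replicate block, 2 to 4 and 0 to 1 with 1 array left out; camera adjusted p = 0.175, fry adjusted p = 0.00572). Of 23 drug-metabolizing cytochrome P450 genes 1, Cyp2b10, was called lower and none higher, with the same counts when adjusted over the list alone and 2 lower with the replicate block, 1 to 3 with 1 array left out. The camera adjusted p was 0.00451, and 0.267 with an estimated correlation, 0.0805 by fry, 0.479 without WT replicates 3 and 4 and 0.0899 with no filter on low values. In bile acid synthesis 2 of 15 were called higher, with the same count when adjusted over the list alone (camera adjusted p = 0.904). One was Cyp7b1, a hydroxylase of the alternative pathway (5.27-fold).

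In fatty acid and triglyceride synthesis 8 of 21 genes were called lower and none higher, with a camera adjusted p of 8.7e-10, and 0.0838 with an estimated correlation. The counts moved (9 and 1 with the replicate block; 3 to 6 lower with 1 array left out, fewest without TrxR1/Gsr-null replicate 2). Of the 21 differences 19 were negative, with a median log2 difference of -0.78. Besides Lpin1, Srebf1, the transcription factor that drives the pathway, fell 2.52-fold and Scd1, the stearoyl-CoA desaturase, 2.19-fold. Without WT replicates 3 and 4 Lpin1 and Srebf1 were not called (adjusted p = 0.0535 and 0.0631). Acly, the ATP citrate lyase, averaged 11.34 in WT and 10.41 in the null livers without being called (adjusted p = 0.0616). Acly was called without TrxR1/Gsr-null replicate 1 (adjusted p = 0.0375), with array weights (0.0116), the mean of its probe sets (0.0177) or a trended, robust prior (0.033), after centring (0.0263) and after quantile normalization (0.0434). Adjusted over the list alone, 13 were lower and 1 higher. Cholesterol synthesis and uptake had 3 of 19 called lower and none higher (7 lower adjusted over the list alone, 6 with the replicate block and 6 without WT replicates 3 and 4). That list's camera adjusted p was 3.4e-07, and 0.267 with an estimated correlation, and fry did not call it (adjusted p = 0.0508). Fdps was 3.31-fold and Sc5d 2.26-fold lower.

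In fatty acid oxidation and PPAR alpha targets 1 of 31 was called higher and 3 lower (3 and 8 adjusted over the list alone, 1 to 2 and 2 to 4 with 1 array left out), and 23 of the 31 differences were negative, with a median log2 difference of -0.23 (-0.40 after centring). The list was called toward lower by camera (adjusted p = 0.00088) and by fry (adjusted p = 0.0159), with adjusted p = 0.123 with an estimated correlation, and 0.138 without WT replicates 3 and 4. Cd36, the fatty acid uptake receptor, rose 7.42-fold, while Cyp4a14 fell as above, Cyp4a31 fell 5.74-fold and Angptl4, an inhibitor of lipoprotein lipase, 4.08-fold. The Angptl4 call (adjusted p = 0.0223) was lost without WT replicate 3 or 4 or TrxR1/Gsr-null replicate 1 or 2 (adjusted p up to 0.0681). Angptl4 is also among the called neighbours of the H2 genes described below, and whether its fall is a difference of strain was not tested. In gluconeogenesis, glycolysis and glycogen 2 of 19 were called higher and 4 lower (3 and 5 adjusted over the list alone, 1 to 3 and 0 to 4 with 1 array left out; camera adjusted p = 0.301, and 0.0301 without probe sets that can match several transcripts). Gbe1, the glycogen branching enzyme, rose 3.64-fold. Pck1, the gluconeogenic PEP carboxykinase, fell 2.35-fold (adjusted p = 0.027), a call lost without WT replicate 2 or 3 or TrxR1/Gsr-null replicate 1 or 2 (adjusted p up to 0.0788), and with the mean of its probe sets (adjusted p = 0.0695). G6pc averaged 11.02 ± 1.07 in WT and 9.28 ± 1.10 in the null livers and was not called (adjusted p = 0.119), though it was with the replicate block (adjusted p = 0.00218), with array weights (adjusted p = 0.0413) and without WT replicate 1 (adjusted p = 0.0471).

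Of 13 periportal genes, which hepatocytes express near the portal vein, 4 were called lower and none higher, with a camera adjusted p of 3.3e-05, and 0.154 with an estimated correlation (5 lower adjusted over the list alone; 2 without WT replicate 2 or 3 or TrxR1/Gsr-null replicate 1 or 2). Hal, the histidine ammonia lyase, was 2.60-fold lower beside Igfbp2. Of 13 pericentral genes 1 was called higher and none lower (2 and 2 adjusted over the list alone and with the replicate block, 0 to 1 and 0 to 1 with 1 array left out). The camera adjusted p was 0.301 with a median of -0.20 on the log2 scale, and 0.0255 with a median of -0.40 without WT replicate 1. Without WT replicate 2 the median was -0.09. All 23 secreted hepatocyte proteins had negative differences and 1 was called lower (0 to 1 with 1 array left out), with the same count when adjusted over the list alone, a median log2 difference of -0.30 (-0.47 after centring), a camera adjusted p of 1.0e-05, and 0.275 with an estimated correlation. Albumin, Alb, averaged 14.32 ± 0.30 in WT and 13.85 ± 0.49 in the null livers and was not called (adjusted p = 0.324).

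In the cytosolic heat shock response 6 of 16 genes were called higher and none lower, with a camera adjusted p of 4.3e-06, and 0.218 with an estimated correlation. Only 3 were called higher without WT replicate 3 or 4 or TrxR1/Gsr-null replicate 4. All 16 differences were positive, with Hsph1 6.11-fold, Hsp90aa1 2.70-fold and Hspb1 7.14-fold higher (4.28-fold without TrxR1/Gsr-null replicate 4, and 3 of its 4 WT values lay below the low-value limit). Adjusted over the list alone, 10 were higher. The Hspb1 call (adjusted p = 0.0229) was lost without WT replicate 3 or 4 (adjusted p up to 0.0656). In the integrated stress response 1 of 22 was called higher, Psat1 of serine synthesis (4.21-fold), and 2 were adjusted over the list alone and 3 with the replicate block, 1 to 2 with 1 array left out. That list's camera adjusted p was 0.0704, toward higher. It was 0.0344 after quantile normalization and 0.0254 after centring, 0.0396 with low values raised to a floor, 0.0441 with the mean of probe sets, 0.00471 with no filter on low values, and 0.0286, 0.0425 and 0.0186 without TrxR1/Gsr-null replicates 1, 2 and 3. Of 21 ER chaperones and unfolded protein response genes 1 was called higher and 1 lower, with the same counts when adjusted over the list alone and 0 to 1 each with 1 array left out (camera adjusted p = 0.551). Of 17 p53 targets none was called in either direction, nor adjusted over the list alone, and 4 had an unadjusted limma p under 0.05 (camera adjusted p = 0.996, fry adjusted p = 0.451). In the acute phase response 2 of 23 were called higher (3 higher and 1 lower adjusted over the list alone, 4 and 1 with the replicate block, 1 to 2 higher with 1 array left out; camera adjusted p = 0.834). Lcn2, an iron-siderophore binding protein, was 8.73-fold higher. Of 24 interferon response genes 1, Usp18, was called lower (2.37-fold, adjusted p = 0.018), with the same count when adjusted over the list alone and 2 with the replicate block, and the call was lost without WT replicate 3 or TrxR1/Gsr-null replicate 2 (adjusted p up to 0.0572). The interferon list had a camera adjusted p of 0.0542 toward lower, 0.0316 with the replicate block, 0.0394 with array weights, 0.0178 without TrxR1/Gsr-null replicate 1, 0.0204 without replicate 3 of that group and 0.0369 without WT replicate 3. In metallothionein, iron and heme 3 of 20 were called higher and 1 lower, with the same counts when adjusted over the list alone and 3 and 2 with the replicate block, 3 and 0 to 1 with 1 array left out (camera adjusted p = 0.321, fry adjusted p = 0.0102, and 0.0141 by camera without probe sets that can match several transcripts). Tfrc, the transferrin receptor, rose 9.96-fold and Alas1, the first enzyme of heme synthesis, 3.92-fold. Hmox1, the inducible heme oxygenase, averaged 3.81 ± 0.73 in WT and 5.26 ± 1.89 in the null livers (SD, n = 4 each) and was not called by limma (adjusted p = 0.314). Its value was 8.05 in TrxR1/Gsr-null replicate 4 against 3.87 to 4.64 in the other null livers, and without that array the log2 difference was 0.52 (adjusted p = 0.492).

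Of 10 fetal and immature liver genes 5 were called higher and none lower, with a camera adjusted p of 0.0131, 0.275 with an estimated correlation and 0.0565 without WT replicate 2. The counts were the same when adjusted over the list alone and 3 higher without TrxR1/Gsr-null replicate 2. Gpc3, a glypican, rose 4.43-fold from a WT mean below the low-value limit, beside Afp and Ly6d. In cell cycle and proliferation 2 of 29 were called higher, with the same count when adjusted over the list alone, 12 without WT replicate 1 and 0 or 1 without any other array, and 24 differences were positive. The camera adjusted p was 0.0161, and 0.682 with an estimated correlation, and 0.223 by fry. Camera gave up to 0.251 without WT replicate 2 or 3, 0.0777 without WT replicates 3 and 4 and 0.12 with the lowest 60% of genes left out. Mki67 averaged 5.84 ± 1.80 in WT and 7.23 ± 0.31 in the null livers and was not called (adjusted p = 0.282), though it was without WT replicate 1 (log2 difference 2.25, adjusted p = 0.00351).

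Of 11 male-biased genes 2 were called higher, Cyp7b1 and Cyp4a12a (11.0-fold from a WT mean below the low-value limit, and 7.09-fold without TrxR1/Gsr-null replicate 4), while the list's median was -0.59 on the log2 scale, -0.38 without WT replicate 2 and -0.33 without WT replicates 3 and 4 (3 higher and 1 lower adjusted over the list alone, 2 and 1 with the replicate block, 2 and 0 to 2 with 1 array left out; camera adjusted p = 0.496). Of 13 female-biased genes none was called and 4 had an unadjusted limma p under 0.05 (2 higher adjusted over the list alone, 1 with the replicate block, 0 to 1 each way with 1 array left out; camera adjusted p = 0.551, fry adjusted p = 0.322). Endothelial markers had 1 of 17 called lower (4 adjusted over the list alone, 3 with the replicate block, 0 to 1 with 1 array left out), with a camera adjusted p of 0.000526, and 0.154 with an estimated correlation. Pecam1 averaged 4.08 in WT and 3.48 in the null livers and was not called, though it was without WT replicates 3 and 4 (adjusted p = 0.0378). Stellate cell, fibroblast and matrix markers had 1 of 17 called lower (2 adjusted over the list alone, 0 to 1 with 1 array left out), with a camera adjusted p of 0.00986, 0.405 with an estimated correlation and 0.223 by fry. Col3a1 averaged 11.60 and 11.29 and was not called. Macrophage and Kupffer cell markers had 1 of 15 called higher and none lower (1 and 1 with the replicate block, 0 to 1 higher with 1 array left out), with the same count when adjusted over the list alone. Their median was -0.15 on the log2 scale (camera adjusted p = 0.119), -0.25 without WT replicate 1 (0.0255), -0.24 without WT replicate 2 (0.0353), -0.23 without TrxR1/Gsr-null replicate 4 (0.0458) and -0.26 within replicates 3 and 4 alone (0.0108). It was -0.02 without WT replicate 4 or TrxR1/Gsr-null replicate 2, and turned to 0.02 without WT replicates 3 and 4. Clec4f averaged 9.33 and 8.85 and was not called. Bile duct and progenitor cell markers had 2 of 8 called higher, with the same count when adjusted over the list alone, 0 without WT replicate 3 or TrxR1/Gsr-null replicate 2 or 4 and 1 without WT replicate 1 or 4 or TrxR1/Gsr-null replicate 1 (camera adjusted p = 0.411). Krt8 averaged 10.45 and 10.87 and was not called. None of 3 neutrophil markers was called and 2 had an unadjusted limma p under 0.05 (2 higher adjusted over the list alone, 1 with the replicate block, 2 without WT replicate 1; camera adjusted p = 0.256). S100a8 averaged 4.11 and 5.41 (adjusted p = 0.0541) and was called with the replicate block (adjusted p = 0.0382), without WT replicate 1 (0.00715), with array weights (0.0165), after centring (0.0326), with the mean of its probe sets (0.0496) and with a trended, robust prior (0.0473). None was called among 4 markers of B, T and NK cells (1 lower adjusted over the list alone; camera adjusted p = 0.254), 3 erythroid markers (camera adjusted p = 0.551) and 1 marker of adipose tissue, muscle and pancreas (camera adjusted p = 0.688), nor, adjusted over the list alone, was any member of the erythroid and adipose lists. Of these 3 lists 2, 0 and 0 members had an unadjusted limma p under 0.05, and fry gave adjusted p = 0.177, 0.649 and 0.732.

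**Figure D4:**
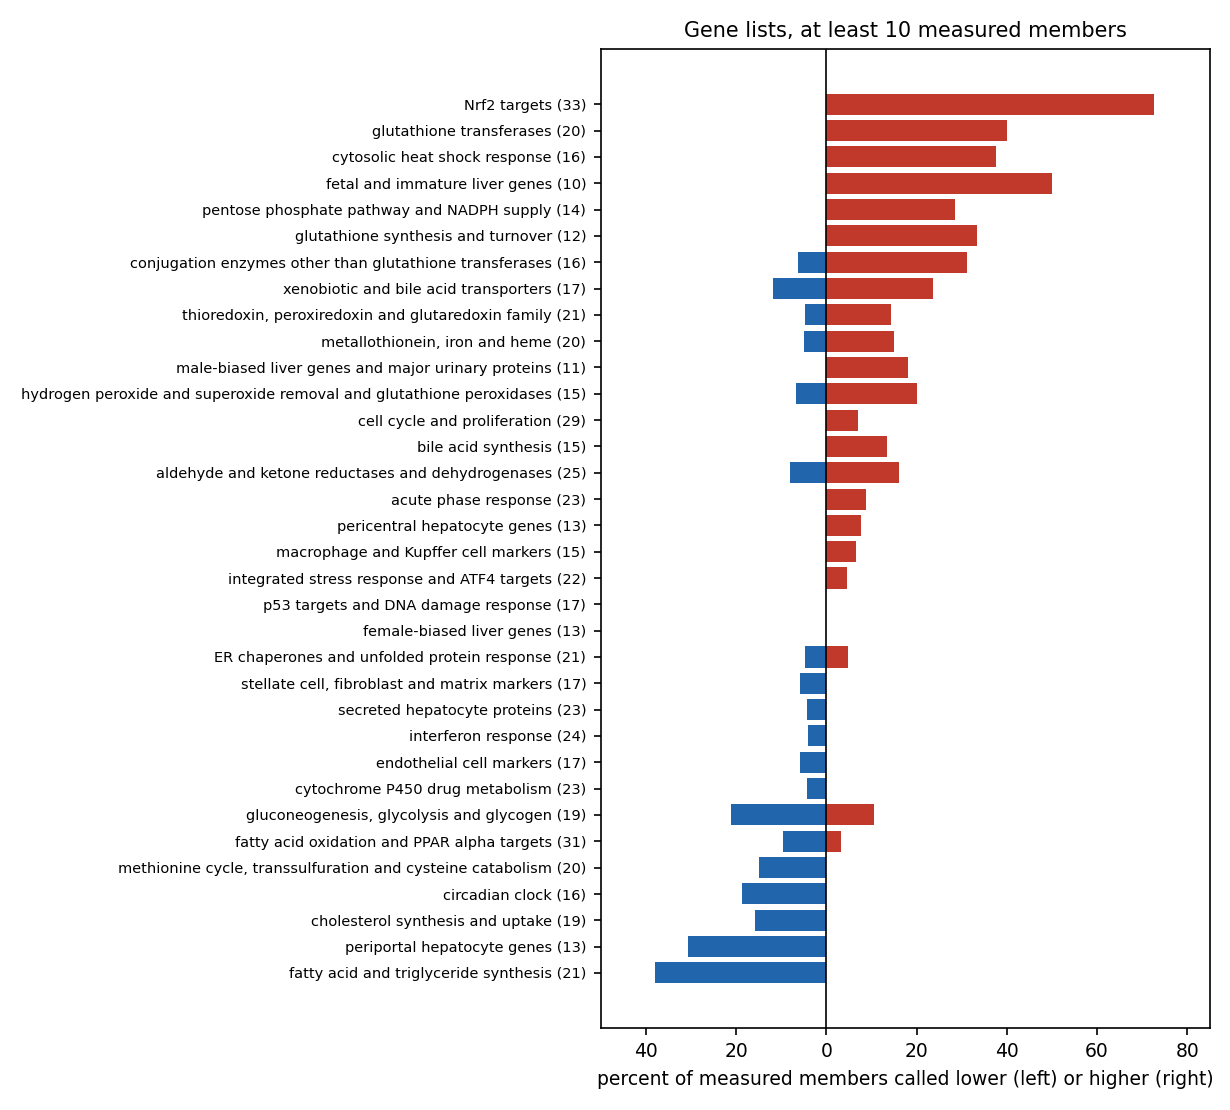
Percent of the measured members of each gene list that were called higher (red, to the right) or lower (blue, to the left) in TrxR1/Gsr-null liver, for lists with at least 10 measured members; the number measured is in parentheses. The bars extend furthest to the right for Nrf2 targets (24 of 33) and furthest to the left for fatty acid and triglyceride synthesis (8 of 21).

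A null allele made in another mouse strain can carry that strain's segment beside it, so the share of called genes among the tested neighbours of Txnrd1 and Gsr was compared with that elsewhere. Among the 50 nearest tested genes on each side, 4 of 100 were called beside Txnrd1 and 9 of 100 beside Gsr, together 6.50%, against 6.61% of 7327 other tested genes. The odds ratio was 0.983 with a 95% interval from 0.510 to 1.74 (Fisher's exact test, two-sided, p = 1). It was 0.586 beside Txnrd1 (p = 0.415, exact) and 1.41 beside Gsr (p = 0.309, exact). Without WT replicate 3 the combined odds ratio was 1.54 and without WT replicates 3 and 4 it was 1.57, neither past the threshold.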

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

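The test for outlying arrays was applied to the log2 values of 80 named genes, 160 sets of 4 values, and to array measures. A set counted when its most distant value's gap to the nearest other, over the range of the set, passed Dixon's 95% critical value; chance puts about 1 set in 20 beyond it, or 8 of 160, and 6 were beyond it. The tests of WT replicates 3 and 4, of antigen presentation, of exchanged labels and of the Txnrd1 transcript were chosen after the result was seen, and that of the H2 neighbours after the H2 values but before its own result.

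Cyp4a14 was at 4.43 in TrxR1/Gsr-null replicate 2 against 7.96 to 8.21 in the other null livers (gap over range 0.934). Snhg11 was at 5.45 in TrxR1/Gsr-null replicate 3 against 7.74 to 7.85 (0.953). Ly6d was at 10.14 in TrxR1/Gsr-null replicate 4 against 9.36 to 9.47 (0.861). Cyp4a31 was at 5.35 in that same liver against 3.29 to 3.61 (0.847). Gsr was at 7.03 in WT replicate 1 against 7.20 to 7.21 (0.950), and Txnrd1 at 9.56 in WT replicate 4 against 9.88 to 9.93 (0.868). Outside the gene tests, 59 of 1120 tested probe sets with several genes or none in the annotation were called between the genotypes.

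The number of called genes, 499, and its lean toward higher genes were weighed together. Of the 35 splits of the 8 arrays into 4 and 4, 1 called as many genes, the genotypes themselves. That share treats the arrays as exchangeable, which the shared structure of the replicate numbers goes against, so it cannot exclude chance. Among the 8 splits that part all 4 pairs, too few for a share under 0.05, the genotypes called 499 and the highest other 0, and the fit with the replicate block called 454 higher and 240 lower. The highest other split of the 35, at 158 genes, set replicates 1 and 2 against replicates 3 and 4 and parted none of the pairs. The lean toward higher genes, 67.5% of calls, was 57.5% without WT replicates 3 and 4. That was the lowest of all 12 ways to leave out 2 arrays of a group (66.0% to 81.4% for the others). The narrower spread of values on those 2 arrays is thus a candidate explanation for part of the lean, beside a true excess of rises. Those arrays also differ in absent controls and Actb ends, and leaving them out leaves null replicates 3 and 4 unmatched. The test cannot say which of these matters.

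At the H2-K1 probe set used, null replicates 1 to 4 were at 6.36, 9.92, 7.0 and 10.91 against 11.66 to 12.77 in WT, and the other 3 H2-K1 probe sets were 2.41-, 2.49- and 8.56-fold lower (adjusted p = 0.00223, 0.017 and 0.0705 over all probe sets). Trim34a was at 2.64, 6.26, 3.73 and 6.05 in the same livers. It is not 1 of the H2 neighbours tested below, so that test says nothing about Trim34a. H2-D1, another class I gene, was singled out after its values were seen. Of its 9 probe sets 2 were called, 1 up from 5.17 to 10.15 and 1 down from 5.58 to 3.50. The 3 brightest H2-D1 probe sets in WT, at 12.34, 12.26 and 9.43, averaged 8.90, 9.10 and 5.73 in the null livers (adjusted p = 0.125, 0.15 and 0.0587). The first of these was at 7.01, 10.92, 6.39 and 11.26 in null replicates 1 to 4. A segment of another strain around the H2 genes may give such readings through mismatched probes, yet 7 of the 134 tested neighbours were called (odds ratio 0.777, 95% interval 0.305 to 1.66), and beside Txnrd1 and Gsr the odds ratio was 0.983; both intervals include 1 and 1.5, so neither was decided. Lower antigen presentation was not decided either, since the mean of B2m, Tap1, Tapbp, Psmb8 and Psmb9 differed by -0.11 log2 units (95% interval -0.71 to 0.49). The null livers share 1 labelled genotype, so it does not by itself account for the spread among them at the brightest H2-K1 and H2-D1 probe sets. For their fall against WT, genotype and strain of the H2 genes cannot be told apart here. A lower amount of the H2-D1 transcript alone would not raise 1 of its probe sets 31.5-fold. That argues against this reading for H2-D1, unless the probe set, which ends in _x_at, reads other genes. The H2-K1 probe sets were all lower. The probe sequences were not used, and neighbouring genes need not differ in expression. Cbs and Angptl4, named above, were among the 7 called neighbours, and genotype and strain were not told apart for them either.

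The rise of Txnrd1 in livers labelled as lacking TrxR1 was weighed against exchanged labels and against a transcript that escapes the deletion. Exchanged group labels would put Gsr higher in the arrays labelled null if its probe sets read the deleted part, which the labels do not give. The Gsr difference was -1.15 (95% interval -1.54 to -0.77), which argues against exchanged labels on that condition. A transcript of the null allele that includes the probed part could be read as a rise, and 15 of the 33 Nrf2 list genes rose by more than Txnrd1 did. This stays open, because the other Txnrd1 probe sets reached a WT mean of at most 2.12, below the low-value limit, and so show nothing about the deleted part.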

How the results depend on the processing

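The fits with replicates 1 and 2 or 3 and 4 alone or as a block, and without WT replicates 3 and 4, were chosen after seeing the data. Txnrd1 stayed called higher and the Nrf2 list stayed called in every setting run (median log2 difference 1.70 to 2.23), and Gsr stayed called lower except within replicates 3 and 4 alone (-1.14, adjusted p = 0.0924, 2 arrays per group; 0.000444 to 0.0924 over all settings). Without probe sets that can match several transcripts, Txnrd1 and the odds ratio had no value. The odds ratio beside Txnrd1 and Gsr passed the threshold in no setting. Genes called higher numbered 196 to 387 with 1 array left out, and genes called lower 75 to 134. At an adjusted p below 0.01 there were 137 higher and 52 lower, without shrinkage 199 and 101, at a fold of at least 2 there were 101 lower, with array weights 578 and 428 (57.5% higher), and with all probe sets tested 531 higher. Centring gave 289 lower (49.7% higher) and quantile normalization 271 lower (53.6% higher). Within replicates 1 and 2 alone 52.99% of calls were higher, and within replicates 3 and 4 alone 84.4% (162 higher, 30 lower). With replicates 1 and 2 against 3 and 4 as a block there were 647 and 334, and without WT replicates 3 and 4 187 higher. Except where fewer arrays or a stricter threshold explains a count by construction, the cause was not tested.

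The replicate block gave 454 higher and 240 lower, of which 315 and 150 were called without it; it changed the calls of 7 of 180 named genes and of 4 of 39 lists, and the ones in the text stand beside their results or under the other observations. Without WT replicates 3 and 4, 36 of the named genes lost their call and 2 gained one, and with 1 array left out 15 to 35 lost it. In 17 of the 39 lists the block moved a count of calls by over 1.5 times, and in 33 of them a single left-out array did. A change between 0 and 1 is enough to pass that rule. Nrf2 targets (23 to 24 higher, 0 to 1 lower) and glutathione transferases (8 higher, 0 to 1 lower) are among the 33 only through such a change. Within replicates 3 and 4 alone camera did not call glutathione synthesis, NADPH supply, conjugation, methionine cycle and clock (adjusted p up to 0.237), nor within replicates 1 and 2 alone cell cycle, cytochrome P450 and clock (adjusted p up to 0.263), and it called macrophage markers within replicates 3 and 4 alone (adjusted p = 0.0108). The median of the circadian clock list turned to 0.021 without TrxR1/Gsr-null replicate 2, the highest value with 1 array left out (lowest -0.18); the cause was not tested. Fry did not call cell cycle, cholesterol synthesis, cytochrome P450 and stellate markers, which camera called, and called, toward higher, thioredoxin family, peroxide removal, transporters, aldehyde and ketone reductases and iron and heme, which camera did not. Median, mean and test differed in sign for transporters, bile acid synthesis, ER chaperones, acute phase response and male-biased genes. Signal over background limits the genes near the low-value limit, where GCRMA sets the scale of a fold. Medians of 6 lists lay so near 0 that rescaling the arrays turned their sign; these were aldehyde and ketone reductases, bile acid synthesis, ER chaperones, peroxide removal, p53 targets and transporters.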

Other observations

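Genes of the circadian clock were named above only in part, and the results of their list are given here. Of 16 measured clock genes 3 were called lower and none higher (1 higher and 3 lower adjusted over the list alone, 1 and 2 with the replicate block), namely Bhlhe40 (5.83-fold lower), the PAR bZIP factor Dbp (4.44-fold, adjusted p = 0.0341) and its relative Tef (2.83-fold, adjusted p = 0.0296). The list's camera adjusted p was 0.0494, with 0.218 from an estimated correlation, 0.0672 from the replicate block and 0.159 without WT replicates 3 and 4, and it missed the threshold without any one of WT replicates 2, 3 and 4 and TrxR1/Gsr-null replicates 2 and 3 (adjusted p up to 0.0785). It also missed the threshold with each of the other filters tried, after either rescaling and with the mean of probe sets (adjusted p up to 0.154). In the setting without Nrf2 list members, of which the clock list has none, its camera adjusted p was 0.0667. The clock list was unchanged there, and only the adjustment over the lists differed. Arntl and Clock, the activators of the loop, had positive differences of 1.13 and 1.00 on the log2 scale and were not called (adjusted p = 0.292 and 0.0688), though Clock was with the replicate block (adjusted p = 0.0299) and without WT replicate 2 (adjusted p = 0.0486). Bhlhe40, Dbp and Tef were not called without WT replicates 3 and 4 (adjusted p = 0.0694, 0.103 and 0.139). Dbp was not called with the replicate block (adjusted p = 0.0591) or with no filter on low values (adjusted p = 0.0543) nor without WT replicate 1 or 3 or TrxR1/Gsr-null replicate 1 or 3 (adjusted p up to 0.099), and Tef not without WT replicate 3 or 4 or TrxR1/Gsr-null replicate 1, 2 or 3 (adjusted p up to 0.0921). No time of harvest is given per animal.

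Nnt, the mitochondrial transhydrogenase, which carries a deletion in C57BL/6J mice, rose from 8.90 ± 0.38 in WT to 10.07 ± 0.17 in the null livers (SD, n = 4 each). Strain and genotype were not told apart for Nnt. H2-Ea, a class II gene that C57BL/6 mice do not express as protein, averaged 2.16 in WT and 4.34 in the null livers at 1 of its 3 probe sets, the only one called. H2-Aa, another class II gene, averaged 5.11 in WT and 7.16 in the null livers at 1 probe set (limma adjusted p = 0.0346 over all probe sets). At its brighter probe set it averaged 9.10 and 9.32 and was not called. H2-Ea and H2-Aa were picked out after their values were seen.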
